A study of Mus musculus with 120 samples.

How the data were processed

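Brain RNA of C57BL/6J mice was sequenced from 120 libraries, 4 mice per group in 30 groups of genotype, region and age, per the labels. Sex was taken from the labels, and each mouse gave 5 regions of 1 age. Libraries were poly(A)-selected and read as 150-nt pairs on a NovaSeq, per the labels' protocols. Reads were demultiplexed with bcl2fastq 2.20.0, trimmed with Trimmomatic 0.33 and aligned with HISAT2 2.1.0 to GRCm38, per the processing tools in the labels. Pairs were counted per gene with featureCounts of Subread 1.6.2, and the deposited values are raw counts of read pairs, not normalized. Per the file headers, the 10-week counts used Ensembl annotation GRCm38.97, pairs with both ends aligned, a mapping quality of at least 10 and reverse strand, and left out multi-mapping pairs and pairs over several genes. The 26-week file gives no command line, so its strand and quality settings are not stated, and values of overlapping and antisense genes there are uncertain, as are those of genes with near-identical copies at both ages. Labels of the 26-week libraries name the line 154Q and 154QKT in their descriptions and 175Q and 175QK772T as genotype, and the genotype field was used.

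Each of the 10 sets of region and age was fitted by itself (12 libraries). Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the genotypes as groups, scaled by TMM and tested with edgeR's quasi-likelihood test with terms for genotype and sex. Contrasts were 175Q against WT, 175QK772T against WT and 175QK772T against 175Q, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 with no limit on the fold. The change of the 175Q effect between ages was tested as an interaction in the 4 regions sampled at both ages. The 29 gene lists were fixed beforehand, and 351 of their 352 genes were matched by symbol; 55394 of 55573 genes had one. They were tested with camera on voom values with a correlation of 0.01 and, as an alternative, an estimated one. The signature score was the mean over 100 genes of log2 CPM (prior count 2) minus the WT mean, signed by the 175Q direction at the other age, and was compared by a two-sided exact permutation test over 70 assignments, adjusted over 30 tests. Enrichment of calls within 10 Mb of Atxn1 used Fisher's exact test. Where a group had no counts the fold was given against a floor of 3 counts over the group.

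Design, gene lists, naming rule and most alternatives were set before the data were examined. Named genes were Atxn1 everywhere, and for 175Q against WT the 8 largest rises and 8 largest falls in cerebellum, brainstem and medulla and 5 of each in the other regions, among called genes with a mean of at least 1 CPM over 12 libraries and no overlap between the 4 values of each group. For the other 2 contrasts 3 of each were named, from each described list up to 4 members of smallest adjusted p, of which 1 is printed, and up to 10 genes called the same way in at least 4 of 5 regions of an age by mean rank. Left out were genes on chromosome Y, Xist, Tsix, symbols that begin with Gm and a digit or end in Rik, and genes with no symbol. A few genes that the rule names are not reported here, and no others were put in their place. The plan was to report every list in every contrast; instead lists are summed over the 10 sets, the described ones are given in full, and the other contrasts as numbers passing. Functions given for genes are general knowledge, not results.

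The alternatives were DESeq2, RLE normalization, no low-count filter, no sex term, a replicate block, each library left out, the shared group split between contrasts, 50 or 300 score genes, windows of 5 and 20 Mb, and fits without doubted libraries. Total counts were 68.2 to 104 M per library at 10 weeks and 28 to 57.3 M at 26 weeks. The edgeR test was tested on simulated data with 50 genes changed at each of 1.25, 1.5, 2 and 4-fold: it recovered 58, 82, 96 and 100% in turn at the depth and spread of the 10-week cerebellum, 0, 16, 62 and 90% for the 26-week cerebellum, 24, 54, 96 and 100% for the 26-week striatum and 0, 16, 52 and 92% for the interaction in the cerebellum. In these simulations 8 of 176, 3 of 87, 8 of 145 and 9 of 89 calls were false. No library was a copy of another of its set. All libraries were kept in the tests, 1 doubted WT library of the 26-week cortex included.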

Results

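RNA was measured in 5 brain regions of a mouse model of spinocerebellar ataxia type 1, an inherited ataxia caused by a lengthened CAG repeat in the ataxin-1 gene. Knock-in 175Q mice carry 1 expanded Atxn1 allele, and in 175QK772T mice that allele also has the K772T change in the nuclear localization signal of ataxin-1. The design asks which changes of 175Q mice depend on that signal. Each genotype had 4 mice at 10 weeks and 4 others at 26 weeks, and each mouse gave 5 regions, so that 120 libraries fell into 30 groups of 4. Cerebellum, cortex, hippocampus and striatum were sampled at both ages, brainstem at 10 weeks and medulla at 26 weeks. The ages were sequenced as separate batches, so genotypes were compared within an age. In brackets after a gene stands its log2 fold change ± its standard error, from edgeR's quasi-likelihood test of 4 against 4 mice with sex as a covariate, and ± after a mean is the SD of 4 mice. Floors and counting intervals cover counting error only. For gene lists the number of called members is given over all genes and adjusted over the list alone, then the median log2 fold change and the adjusted p of camera with a fixed and with an estimated correlation between genes.

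Atxn1, the gene that carries the knock-in (ENSMUSG00000046876, GRCm38 chromosome 13, 45549755 to 45965008, minus strand), was checked first. In the brainstem at 10 weeks it was at 34.2 ± 0.292 CPM in WT, 42.8 ± 1.42 in 175Q and 43.6 ± 1.32 in 175QK772T. At 10 weeks it rose against WT in both mutants in 4 regions: log2 fold changes in 175Q and 175QK772T were 0.15 ± 0.03 and 0.32 ± 0.04 in cerebellum, 0.32 ± 0.04 and 0.35 ± 0.04 in brainstem, 0.10 ± 0.04 and 0.20 ± 0.04 in cortex and 0.27 ± 0.05 and 0.40 ± 0.05 in hippocampus (edgeR adjusted p at most 0.0257). In the striatum at 10 weeks they were -0.05 ± 0.06 and 0.10 ± 0.06 (edgeR adjusted p = 0.548 and 0.251). At 26 weeks Atxn1 rose in both mutants in the medulla (0.38 ± 0.06 and 0.34 ± 0.06, edgeR adjusted p = 0.000733 and 0.00888) and in 175QK772T in the hippocampus (0.31 ± 0.07, edgeR adjusted p = 0.00488), and the other comparisons with WT did not pass. 175QK772T was above 175Q in the cerebellum at 10 weeks (0.17 ± 0.04, edgeR adjusted p = 0.0251). Gene counts do not separate the knock-in allele from the normal one.

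**Figure D1:**
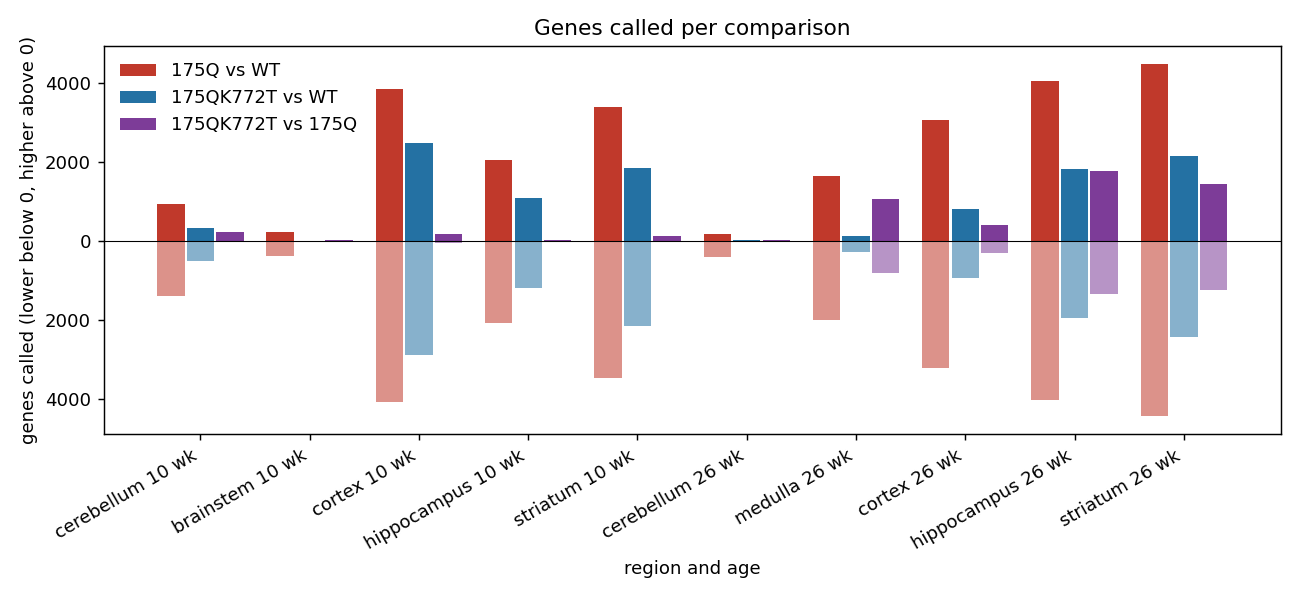
Genes called at adjusted p below 0.05 by edgeR (vertical axis, number of genes, higher above 0 and lower below 0) in each region and age (horizontal axis), for 3 comparisons of genotypes with 4 mice each. For 175Q against WT in the striatum at 26 weeks, 4479 genes were higher and 4452 lower.

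In the cerebellum at 10 weeks, all 14 measured markers of Purkinje cells, the output neurons of the cerebellar cortex, fell in 175Q mice. The largest rises were in Ankdd1a (1.90 ± 0.22), Fam163b (1.49 ± 0.22), Sfrp4 (1.41 ± 0.09), Mndal (1.4 ± 0.14), Zfp92 (1.33 ± 0.32), Rprm (1.30 ± 0.13), Slc44a5 (1.20 ± 0.09) and Kcnb2 (1.15 ± 0.12). The largest falls were in Myo15 (-3.98 ± 0.24), Car9 (-2.84 ± 0.12), Kcnh3, a potassium channel (-2.50 ± 0.18), Unc13d (-2.08 ± 0.11), Mdfi (-1.93 ± 0.12), Ccdc63 (-1.88 ± 0.12), Mirt1 (-1.88 ± 0.11) and Tssk5 (-1.81 ± 0.18) (edgeR adjusted p of all named at most 0.0144). Of 14 Purkinje cell markers, 14 fell, or 14 over the list alone (median -0.58, camera adjusted p = 3.12e-28 and 0.0476). Among them was Rgs8 (-0.86 ± 0.04). Among 12 granule cell markers, 7 fell, 1 rose and 4 did not pass, or 9 over the list alone (median -0.22, camera adjusted p = 4.13e-06 and 0.232). These included Cbln1 (-0.56 ± 0.06). By edgeR 2330 of 20447 tested genes were called, 937 higher and 1393 lower.

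At 10 weeks, 13 of the 14 Purkinje cell markers were higher in the 175QK772T than in the 175Q cerebellum. For Purkinje cell markers, 13 of 14 rose and 1 did not pass, or 14 over the list alone (median 0.39, camera adjusted p = 1.06e-37 and 0.0125). Among them was Rgs8 (0.57 ± 0.04). Against 175Q, 244 genes were called, 228 higher and 16 lower in 175QK772T, and 230 were called the opposite way in 175Q against WT. Relative to 175Q, Muc3a (1.54 ± 0.10), Mdfi (1.52 ± 0.12) and Slc15a2 (1.31 ± 0.29) were highest and Aass (-0.50 ± 0.10), Scand1 (-0.42 ± 0.08) and Nmi (-0.35 ± 0.08) were lowest (edgeR adjusted p at most 0.044). Against WT, edgeR called 826 genes in 175QK772T, 319 higher and 507 lower, of which 727 were called the same way in 175Q. Against WT, expression rose most in Fos, an immediate early transcription factor (1.95 ± 0.40), Ankdd1a (1.65 ± 0.22) and Mndal (1.30 ± 0.14) and fell most in Myo15 (-2.70 ± 0.22), Car9 (-2.55 ± 0.12) and Ccdc63 (-1.86 ± 0.12) (edgeR adjusted p at most 0.012). The signature score was 0.956 ± 0.0189 in 175Q and 0.572 ± 0.0307 in 175QK772T, 59.8% of the 175Q mean. The counts changed to 148 without 175Q replicate 1 against 175Q, and to 514 without 175QK772T replicate 4 against WT. Leaving out 1 library ended the call of Slc15a2 (any but 175QK772T replicate 2 and 175Q replicate 1), Aass (any but 175Q replicates 2 and 4), Scand1 (175Q replicate 2), Nmi (any 1 of the 8) and Fos (175QK772T replicate 4) (edgeR adjusted p up to 0.192).

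At 26 weeks 9 of 14 Purkinje cell markers were lower in the 175Q cerebellum. Genes that rose most were Ankdd1a (2.52 ± 0.43), Fam163b (2.28 ± 0.18), Zfp92 (2.13 ± 0.45), Hrk, an activator of apoptosis (1.81 ± 0.12), Sfrp4 (1.65 ± 0.26), Mndal (1.54 ± 0.26), Slc44a5 (1.51 ± 0.27) and Gpr179 (1.45 ± 0.19). Genes that fell most were Myo15 (-4.45 ± 0.34), Kcnh3 (-3.09 ± 0.71), Car9 (-2.94 ± 0.24), Mirt1 (-2.36 ± 0.47), Muc3a (-2.27 ± 0.42), Ly6g6e (-2.27 ± 0.26), Rasal1 (-2.15 ± 0.21) and Ccdc63 (-2.07 ± 0.20) (edgeR adjusted p of all at most 0.041). Of 14 Purkinje cell markers, 9 fell and 5 did not pass, or 11 over the list alone (median -0.64, camera adjusted p = 2.65e-16 and 0.0252). These included Stac (-1.43 ± 0.12). edgeR called 576 of 19156 tested genes, 169 higher and 407 lower. The count was 344, 202, 232 and 225 without WT replicates 1 to 4 in turn and 208 and 242 without 175Q replicates 1 and 2. The call of Ankdd1a (WT replicate 2), Zfp92 (any but 175Q replicate 4 and WT replicate 1), Slc44a5 (WT replicates 2 and 4), Kcnh3 (any but WT replicates 1 and 3), Mirt1 (any but 175Q replicates 3 and 4) and Muc3a (WT replicates 2 and 3 and 175Q replicates 1 and 2) was lost without 1 library (edgeR adjusted p up to 0.119). Kcnh3 gave -1.76 without WT replicate 1. Mitochondrial transcripts made up 13.5% of counts in 175Q replicate 4 and 11.5% in 175QK772T replicate 2, against 3.89 to 5.01% in the other 10 libraries. Without these 2 libraries, an alternative added after seeing the data, 2608 genes were called (1110 higher).

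The Purkinje cell markers were higher in 175QK772T than in 175Q as a list in the 26-week cerebellum, and 1 passed by itself. Among 14 Purkinje cell markers, 1 rose and 13 did not pass, or 6 over the list alone (median 0.42, camera adjusted p = 2.09e-10 and 0.0856). Among them was Stac (0.88 ± 0.12). 175QK772T against 175Q had 19 called genes, 17 higher and 2 lower, of which 19 were called the opposite way in 175Q against WT. In that comparison Mycbpap (1.25 ± 0.19), Dlx4os (1.03 ± 0.16) and Slc7a3 (1.03 ± 0.13) were highest and Hrk (-1.25 ± 0.12) was lowest (edgeR adjusted p at most 0.0492). 175QK772T had 57 called genes against WT, 13 higher and 44 lower, and 52 of these were called the same way in 175Q. Relative to WT, expression rose most in Fam163b (1.6 ± 0.18) and Synpr (1.09 ± 0.11) and fell most in Myo15 (-4.26 ± 0.34), Car9 (-2.84 ± 0.24) and Il20rb (-2.26 ± 0.28) (edgeR adjusted p at most 0.00516). Signature scores were 1.14 ± 0.0549 in 175Q and 0.776 ± 0.0381 in 175QK772T, 68.3% of the 175Q mean. The counts changed to 5, 2, 1 and 4 without 175QK772T replicates 1 to 4 in turn and 2, 1, 2 and 44 without 175Q replicates 1 to 4 in turn against 175Q, and to 35, 16, 19 and 23 without WT replicates 1 to 4 in turn and 26, 26, 18 and 20 without 175QK772T replicates 1 to 4 in turn against WT. With 1 library left out, edgeR no longer called Mycbpap (any but 175Q replicate 4), Dlx4os (any but 175Q replicate 4) and Slc7a3 (any but 175Q replicates 1 and 4) (adjusted p up to 0.295). Without the 2 libraries of high mitochondrial share the counts were 1682 against 175Q (994 higher) and 702 against WT (321 higher). The other gene lower than in 175Q, named after its value was seen, was 9430034N14Rik (-1.63 ± 0.23).

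In the 175Q brainstem at 10 weeks, genes of noradrenaline synthesis and transport were among those that fell most. The strongest increases were those of Usp18 (1.18 ± 0.24), Ifi27l2a (1.15 ± 0.18), Irf7 (1.14 ± 0.17), Ifit1 (1.09 ± 0.17), Ddx60 (1.07 ± 0.19), Ifit3 (1.02 ± 0.18), Oasl2 (0.91 ± 0.17) and Ppp1r1c (0.89 ± 0.16). The strongest decreases were those of Slc6a2, the noradrenaline transporter (-2.99 ± 0.38), Dbh, dopamine beta-hydroxylase of noradrenaline synthesis (-1.94 ± 0.26), Chrna6 (-1.66 ± 0.38), Prok1 (-1.51 ± 0.19), Crh, corticotropin-releasing hormone (-1.39 ± 0.16), Lrrc74b (-1.17 ± 0.28), Th, tyrosine hydroxylase of catecholamine synthesis (-1.09 ± 0.19) and Slc18a2, the vesicular monoamine transporter (-1.08 ± 0.22) (edgeR adjusted p of all at most 0.0394). For monoaminergic neuron genes, 4 of 10 fell and 6 did not pass, or 4 over the list alone (median -0.57, camera adjusted p = 1.41e-05 and 0.197). These included Slc6a2 (-2.99 ± 0.38). Of 12 astrocyte markers, 6 fell and 6 did not pass, or 9 over the list alone (median -0.26, camera adjusted p = 2.58e-12 and 0.0876). Among them was Slc1a2, the main astrocyte glutamate transporter (-0.56 ± 0.05). By edgeR 619 of 21130 tested genes were called, 223 higher and 396 lower. With 1 library left out it was 388 and 394 without WT replicates 2 and 4 and 242, 203, 296 and 275 without 175Q replicates 1 to 4 in turn. Calls lost without 1 library were those of Usp18 (any but 175Q replicate 4 and WT replicate 2), Oasl2 (175Q replicate 2), Chrna6 (any but 175Q replicate 1 and WT replicate 3), Lrrc74b (any but WT replicate 2) and Slc18a2 (WT replicate 4 and 175Q replicates 1 and 2) (edgeR adjusted p up to 0.125). Ttr, a choroid plexus transcript, was at 36.4, 60.8, 4810 and 2100 CPM in WT replicates 1 to 4 and 714, 42.5, 39.3 and 60.8 CPM in 175Q, and of 12 choroid plexus genes 0 were called (median -2.67, camera adjusted p = 0.0323 and 0.623).

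In the brainstem at 10 weeks, 2 of 12 astrocyte markers were higher in 175QK772T than in 175Q. Among 12 astrocyte markers, 2 rose and 10 did not pass, or 6 over the list alone (median 0.17, camera adjusted p = 2.38e-14 and 0.0555). These included Slc1a2 (0.34 ± 0.05). Against 175Q, 12 genes were called, 11 higher and 1 lower in 175QK772T, and 12 were called the opposite way in 175Q against WT. Relative to 175Q, Hsd11b1 (0.57 ± 0.06), Slc1a2 (0.34 ± 0.05) and Slc6a11 (0.29 ± 0.04) were highest and Polr2a, the largest subunit of RNA polymerase II (-0.21 ± 0.03) was lowest (edgeR adjusted p at most 0.0405). Against WT, edgeR called 7 genes in 175QK772T, 1 higher and 6 lower, of which 7 were called the same way in 175Q. Against WT, expression rose most in Atxn1 (0.35 ± 0.04) and fell most in Prok1 (-1.25 ± 0.19), Crh (-1.22 ± 0.16) and Igfbp5 (-0.54 ± 0.06) (edgeR adjusted p at most 0.0449). The signature score was 0.468 ± 0.0549 in 175Q and 0.217 ± 0.118 in 175QK772T, 46.3% of the 175Q mean. The counts changed to 2, 1, 2 and 3 without 175QK772T replicates 1 to 4 in turn and 1, 1, 4 and 2 without 175Q replicates 1 to 4 in turn against 175Q, and to 4, 11 and 4 without WT replicates 1, 3 and 4 and 3 and 3 without 175QK772T replicates 1 and 3 against WT. Leaving out 1 library ended the call of Slc1a2 (any but 175QK772T replicate 4), Slc6a11 (any 1 of the 8), Polr2a (any 1 of the 8), Prok1 (any but 175QK772T replicate 4) and Crh (WT replicate 1 and 175QK772T replicates 1, 3 and 4) (edgeR adjusted p up to 0.277). For the score of 175QK772T against WT the two-sided exact permutation p was 0.0571.

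In the 26-week medulla, 7 of 10 monoaminergic neuron, 10 of 12 astrocyte and 7 of 7 ependymal genes fell in 175Q mice. The others did not pass. The largest rises were in Hoxb9 (4.18 ± 0.36), Spag6 (2.1 ± 0.14), Hoxa7 (1.90 ± 0.10), Ppp1r1c (1.54 ± 0.20), Uts2 (1.47 ± 0.27), BC046251 (1.45 ± 0.24) and Acy3 (1.24 ± 0.13). The largest falls were in Htr5b (-2.98 ± 0.15), Crh (-2.41 ± 0.16), Ano2 (-2.01 ± 0.21), Slc6a2 (-1.91 ± 0.17), C1ql1 (-1.88 ± 0.15), Ighm (-1.79 ± 0.21) and Tnfrsf25 (-1.73 ± 0.29) (edgeR adjusted p of all named at most 0.00187). Over the list alone, 9 monoaminergic neuron genes fell (median -0.81, camera adjusted p = 6.25e-06 and 0.194, not passing). Among them was Slc6a2 (-1.91 ± 0.17). As a list alone, 10 astrocyte markers fell (median -0.53, camera adjusted p = 2.44e-13 and 0.0329). These included Slc1a2 (-1.09 ± 0.06). Over the list alone, 7 ependymal cell markers fell (median -0.82, camera adjusted p = 0.000103 and 0.221, not passing). Among them was Foxj1 (-0.68 ± 0.12). edgeR called 3663 of 19787 tested genes, 1643 higher and 2020 lower. The count was 2323 without 175Q replicate 4. Ttr, a choroid plexus transcript, was at 2560, 3430, 964 and 2560 CPM in WT replicates 1 to 4 and 2630, 279, 43.5 and 179 CPM in 175Q, and of 12 choroid plexus genes 0 were called (median -1.61, camera adjusted p = 0.000166 and 0.36).

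In the 26-week medulla, 7 of 12 astrocyte markers were higher in 175QK772T than in 175Q. For astrocyte markers, 7 of 12 rose and 5 did not pass, or 10 over the list alone (median 0.23, camera adjusted p = 3.71e-08 and 0.131). These included Slc1a2 (0.41 ± 0.06). 175QK772T against 175Q had 1872 called genes, 1057 higher and 815 lower, of which 1356 were called the opposite way in 175Q against WT. In that comparison Htr5b (1.91 ± 0.15), Ano2 (1.57 ± 0.21) and Nat8f5 (1.52 ± 0.29) were highest and Plin4 (-1.33 ± 0.26), Hif3a (-1.32 ± 0.12) and Uts2 (-1.14 ± 0.27) were lowest (edgeR adjusted p at most 0.0189). 175QK772T had 412 called genes against WT, 111 higher and 301 lower, and 333 of these were called the same way in 175Q. Relative to WT, expression rose most in Hoxb9 (4.14 ± 0.36), Ppp1r1c (1.57 ± 0.20) and Hoxd8 (1.47 ± 0.24) and fell most in Prg4 (-2.27 ± 0.48), Crh (-2.04 ± 0.16) and Gcg (-1.52 ± 0.29) (edgeR adjusted p at most 0.0216). Signature scores were 0.694 ± 0.0523 in 175Q and 0.414 ± 0.0433 in 175QK772T, 59.7% of the 175Q mean. The counts changed to 1134 and 1101 without 175QK772T replicates 1 and 4 and 830 and 730 without 175Q replicates 1 and 4 against 175Q, and to 237, 241 and 210 without WT replicates 1, 3 and 4 and 926 and 221 without 175QK772T replicates 2 and 4 against WT. The call of Uts2 (175Q replicates 1 and 3) and Prg4 (any but 175QK772T replicates 2 and 3 and WT replicate 2) was lost without 1 library (edgeR adjusted p up to 0.0717).

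In the 10-week cortex, all 12 astrocyte markers and 11 of 12 GABAergic neuron genes fell in 175Q mice. Genes that rose most were Pou4f1 (6.43 ± 0.30), Pax2 (4.76 ± 0.22), Twist1 (3.63 ± 0.15), Wt1 (3.20 ± 0.31) and Tal1 (3.19 ± 0.10). Genes that fell most were Adam33 (-3.98 ± 0.12), Slc23a3 (-3.68 ± 0.18), Olfr464 (-3.39 ± 0.23), Arr3 (-3.36 ± 0.28) and Tnnc1 (-3.17 ± 0.16) (edgeR adjusted p of all at most 4.39e-07). Over the list alone, 12 astrocyte markers fell (median -0.40, camera adjusted p = 4.42e-08 and 0.0628, not passing). Among them was Slc1a2 (-0.57 ± 0.04). Over the list alone, 11 GABAergic neuron genes fell (median -0.39, camera adjusted p = 7.22e-07 and 0.0628, not passing). These included Npy, neuropeptide Y (-1.22 ± 0.05). By edgeR 7936 of 20748 tested genes were called, 3848 higher and 4088 lower.

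In the 10-week cortex, 7 of 12 astrocyte markers were higher in 175QK772T than in 175Q. The other 5 did not pass, and 10 rose over the list alone (median 0.21, camera adjusted p = 2.94e-14 and 0.0516, not passing). Among them was Slc1a2 (0.28 ± 0.04). Against 175Q, 217 genes were called, 157 higher and 60 lower in 175QK772T, and 206 were called the opposite way in 175Q against WT. Relative to 175Q, Rps27a-ps2 (1.81 ± 0.37), Wnt2b (0.84 ± 0.17) and Hbb-bt (0.72 ± 0.15) were highest and En2, a homeobox factor (-1.09 ± 0.15), Pax2 (-0.96 ± 0.17) and Twist1 (-0.86 ± 0.13) were lowest (edgeR adjusted p at most 0.0344). Against WT, edgeR called 5364 genes in 175QK772T, 2458 higher and 2906 lower, of which 4864 were called the same way in 175Q. Against WT, expression rose most in Pou4f1 (5.67 ± 0.32), Pax2 (3.80 ± 0.23) and Wt1 (2.84 ± 0.32) and fell most in Adam33 (-3.47 ± 0.12), Plk5 (-3.15 ± 0.11) and Olfr464 (-3.13 ± 0.23) (edgeR adjusted p at most 4.03e-06). The signature score was 1.12 ± 0.0485 in 175Q and 0.89 ± 0.0237 in 175QK772T, 79.7% of the 175Q mean. The count against 175Q changed to 121, 92 and 72 without 175QK772T replicates 1, 2 and 3 and 34, 53 and 109 without 175Q replicates 1, 2 and 4. With 1 library left out, edgeR no longer called Rps27a-ps2 (any but 175QK772T replicates 2 and 4 and 175Q replicate 3), Wnt2b (175QK772T replicates 2 and 3 and 175Q replicates 1 and 2), Hbb-bt (any but 175QK772T replicate 2 and 175Q replicate 3) and Pax2 (175Q replicates 1 and 2) (adjusted p up to 0.131). Rps27a-ps2 is a pseudogene whose reads can come from its parent gene, so its value is uncertain.

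In the cortex at 26 weeks, the homeobox genes Barx1, Vax2, Hoxc8 and Hoxb9 were among those that rose most in 175Q mice. Capicua targets and cholesterol synthesis genes fell. The strongest increases were those of Pax1 (5.25 ± 0.26). Barx1 (at least 845-fold), Vax2 (at least 208-fold) and Hoxc8 (at least 177-fold) rose from 0 counts in the WT libraries, with a floor of 3 counts over the group. Hoxb9 had 1017 counts over the 4 175Q libraries against 2 in the other group, a ratio of 524 with a 95% exact binomial interval of 145 to 4340. The strongest decreases were those of Arr3 (-4.85 ± 0.54), Fst, follistatin (-4.43 ± 0.49), Chat, choline acetyltransferase (-3.83 ± 1.19), Scn4b (-3.71 ± 0.38) and Ankrd63 (-3.67 ± 0.36) (edgeR adjusted p of all at most 0.029). Of 13 targets of the repressor Capicua, 11 fell and 2 did not pass, or 11 over the list alone (median -0.88, camera adjusted p = 5.27e-06 and 0.236). These included Etv4 (-1.02 ± 0.10). Among 23 cholesterol synthesis genes, 19 fell and 4 did not pass, or 19 over the list alone (median -0.53, camera adjusted p = 4.82e-08 and 0.231). Among them was Hmgcs1 (-0.66 ± 0.06). edgeR called 6275 of 19888 tested genes, 3044 higher and 3231 lower. Calls lost without 1 library were those of Chat (175Q replicates 3 and 4) (edgeR adjusted p up to 0.118). WT replicate 1, labelled female, stood apart from the other WT cortex libraries: the male transcript Ddx3y was at 70.2 CPM and the glycine transporter gene Slc6a5 at 405 CPM, against 0.121 ± 0.118 in the other 3. Without it 9076 genes were called and Chat gave -1.39. The gene list tests were not run without this library.

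In the 26-week cortex, Capicua targets were higher in 175QK772T than in 175Q as a list, and 3 of 13 passed by themselves. For targets of the repressor Capicua, 3 of 13 rose and 10 did not pass, or 11 over the list alone (median 0.71, camera adjusted p = 1.46e-08 and 0.15). These included Etv4 (0.83 ± 0.10). 175QK772T against 175Q had 688 called genes, 381 higher and 307 lower, of which 657 were called the opposite way in 175Q against WT. In that comparison Ier5l (1.76 ± 0.20), Tnfrsf25 (1.62 ± 0.30) and Trpv6 (1.5 ± 0.28) were highest and Asf1b (-1.35 ± 0.20), Hoxb9 (-1.33 ± 0.24) and Ccer2 (-1.31 ± 0.24) were lowest (edgeR adjusted p at most 0.0189). 175QK772T had 1756 called genes against WT, 796 higher and 960 lower, and 1663 of these were called the same way in 175Q. Relative to WT, expression fell most in H2-Bl (-3.46 ± 0.46), Fst (-3.35 ± 0.46) and Ecel1 (-3.18 ± 0.90) (edgeR adjusted p at most 0.0486). Barx1 (at least 652-fold), Vax2 (at least 106-fold) and Hoxc8 (at least 106-fold) rose from 0 counts in the WT libraries, with a floor of 3 counts over the group. Signature scores were 1.6 ± 0.0614 in 175Q and 1.09 ± 0.046 in 175QK772T, 67.6% of the 175Q mean. The counts changed to 163, 138, 245 and 226 without 175QK772T replicates 1 to 4 in turn and 238, 197, 325 and 119 without 175Q replicates 1 to 4 in turn against 175Q, and to 4641 without WT replicate 1 and 1039, 930, 995 and 1011 without 175QK772T replicates 1 to 4 in turn against WT. Leaving out 1 library ended the call of Tnfrsf25 (any but 175QK772T replicates 3 and 4 and 175Q replicate 3), Trpv6 (any but 175QK772T replicate 3 and 175Q replicate 3), Hoxb9 (any but 175QK772T replicate 2 and 175Q replicate 3), Ccer2 (any but 175QK772T replicate 1 and 175Q replicates 2 and 3) and Ecel1 (175QK772T replicates 1 to 4) (edgeR adjusted p up to 0.168). Ecel1 gave -1.27 without WT replicate 1. With WT replicate 1 also left out of the fit against 175Q, an alternative added after seeing the data, 4738 genes were called.

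In the 10-week hippocampus, 14 of 15 glutamatergic synapse genes and 9 of 11 dentate gyrus and CA field markers fell in 175Q mice. The others did not pass. The largest rises were in Pou4f1 (6.42 ± 0.32), Skor1 (5.25 ± 0.22), Pax2 (4.77 ± 0.30), Igf2os (3.59 ± 0.28) and Twist1 (2.91 ± 0.18). The largest falls were in Plk5 (-2.96 ± 0.13), Ankrd63 (-2.65 ± 0.12), Pla2g2f (-2.45 ± 0.32), Itga11 (-2.34 ± 0.18) and Dio3 (-2.28 ± 0.50) (edgeR adjusted p of all named at most 0.00626). Over the list alone, 9 dentate gyrus and CA field markers fell (median -0.44, camera adjusted p = 2.42e-08 and 0.102, not passing). Among them was C1ql2 (-1.92 ± 0.10). Over the list alone, 14 glutamatergic synapse genes fell (median -0.32, camera adjusted p = 7.59e-13 and 0.076, not passing). These included Camk2a (-0.77 ± 0.06). By edgeR 4132 of 21071 tested genes were called, 2046 higher and 2086 lower.

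In the hippocampus at 10 weeks, edgeR called Skor1, Twist1 and Tbx2 lower in 175QK772T than in 175Q, but chance was not excluded. Against 175Q, 7 genes were called, 2 higher and 5 lower in 175QK772T, and 7 were called the opposite way in 175Q against WT. Of 35 splits of these libraries into 4 and 4, the real one included, 4 called at least as many genes. Relative to 175Q, Dio2 (0.40 ± 0.04) and Ddn (0.35 ± 0.05) were highest and Skor1 (-1.5 ± 0.17), Twist1 (-1.27 ± 0.17) and Tbx2 (-1.06 ± 0.15) were lowest (edgeR adjusted p at most 0.0465). Against WT, edgeR called 2273 genes in 175QK772T, 1072 higher and 1201 lower, of which 2059 were called the same way in 175Q. Against WT, expression rose most in Pou4f1 (5.33 ± 0.33), Pax2 (4.11 ± 0.30) and Skor1 (3.75 ± 0.22) and fell most in Plk5 (-2.48 ± 0.13), Htra4 (-2.00 ± 0.18) and Ankrd63 (-1.96 ± 0.12) (edgeR adjusted p at most 2.75e-05). The signature score was 1.11 ± 0.0782 in 175Q and 0.786 ± 0.0569 in 175QK772T, 70.5% of the 175Q mean. The counts changed to 2, 2 and 1 without 175QK772T replicates 1, 2 and 4 and 1 and 2 without 175Q replicates 1 and 2 against 175Q, and to 1317 and 1376 without WT replicates 1 and 3 and 1271 without 175QK772T replicate 4 against WT. The call of Ddn (any but 175Q replicate 4), Skor1 (175QK772T replicate 4 and 175Q replicates 1 and 2), Twist1 (any but 175Q replicates 3 and 4) and Tbx2 (any but 175QK772T replicate 3 and 175Q replicate 3) was lost without 1 library (edgeR adjusted p up to 0.258). The other 2 lower genes, Hoxd8 and Hoxa5, were named after their values were seen and had a mean CPM under 1.

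In the hippocampus at 26 weeks, 5 Hox genes rose from 0 counts in 175Q mice, and all 11 measured dentate gyrus and CA field markers fell. Hoxb9 (at least 634-fold), Hoxa5 (at least 375-fold), Hoxd9 (at least 244-fold), Hoxc13 (at least 241-fold) and Hoxc4 (at least 194-fold) rose from 0 counts in the WT libraries, with a floor of 3 counts over the group. Genes that fell most were C1ql2 (-4.15 ± 0.23), Ankrd63 (-4.09 ± 0.27), Dio3 (-4.05 ± 0.42), Tnfrsf25 (-4.02 ± 0.27) and Lct (-3.88 ± 0.21) (edgeR adjusted p of all at most 3.64e-06). For dentate gyrus and CA field markers, 11 of 11 fell, or 11 over the list alone (median -1.69, camera adjusted p = 2.89e-09 and 0.0505). Among them was Lct (-3.88 ± 0.21). Of 15 glutamatergic synapse genes, 14 fell and 1 did not pass, or 14 over the list alone (median -0.82, camera adjusted p = 1.99e-10 and 0.0589). These included Camk2a (-1.45 ± 0.06). Among 13 targets of the repressor Capicua, 12 fell and 1 did not pass, or 12 over the list alone (median -0.65, camera adjusted p = 1.3e-07 and 0.0589). Among them was Dusp4 (-1.79 ± 0.12). edgeR called 8073 of 19809 tested genes, 4030 higher and 4043 lower.

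In the 26-week hippocampus, all 13 measured Capicua targets were higher in 175QK772T than in 175Q. For targets of the repressor Capicua, 13 of 13 rose, or 13 over the list alone (median 0.50, camera adjusted p = 5.09e-12 and 0.0201). These included Etv4 (1.12 ± 0.10). Of 11 dentate gyrus and CA field markers, 7 rose and 4 did not pass, or 7 over the list alone (median 0.44, camera adjusted p = 2.04e-05 and 0.0885). Among them was Fibcd1 (1.00 ± 0.10). 175QK772T against 175Q had 3107 called genes, 1759 higher and 1348 lower, of which 2747 were called the opposite way in 175Q against WT. In that comparison Dio3 (2.68 ± 0.44), Ecel1 (2.40 ± 0.49) and Gpr101 (1.79 ± 0.39) were highest and Lbx1 (-2.46 ± 0.28) and Hoxd9 (-2.37 ± 0.23) were lowest (edgeR adjusted p at most 0.00765). 175QK772T had 3765 called genes against WT, 1802 higher and 1963 lower, and 3364 of these were called the same way in 175Q. Relative to WT, expression fell most in Olfr539 (-3.25 ± 0.30), Pla2g2f (-2.86 ± 0.39) and Dsp (-2.71 ± 0.22) (edgeR adjusted p at most 0.000138). Hoxc13 (at least 223-fold), Hoxb9 (at least 182-fold) and Hoxa5 (at least 156-fold) rose from 0 counts in the WT libraries, with a floor of 3 counts over the group. Signature scores were 1.72 ± 0.0484 in 175Q and 1.32 ± 0.0307 in 175QK772T, 76.8% of the 175Q mean. The count against 175Q changed to 1982 without 175QK772T replicate 2.

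In the striatum at 10 weeks, 15 of 16 markers of striatal projection neurons, the main neurons of this region, fell in 175Q mice. Genes that rose most were Wt1 (7.36 ± 0.35), Pou4f1 (4.56 ± 0.27), Dsp (3.27 ± 0.36), Crnde (2.35 ± 0.17) and Ifnlr1 (2.25 ± 0.28). The strongest decreases were those of Gpx6 (-5.86 ± 0.36), Sec14l3 (-4.45 ± 0.32), Abhd11os (-4.32 ± 0.26), Tmprss6 (-4.00 ± 0.47) and Ptpn7 (-3.49 ± 0.19) (edgeR adjusted p of all at most 5.76e-05). Among 16 striatal projection neuron markers, 15 fell and 1 did not pass, or 15 over the list alone (median -1.39, camera adjusted p = 5.54e-14 and 0.247). These included Adora2a, an adenosine receptor (-2.04 ± 0.10). For cholesterol synthesis genes, 18 of 23 fell and 5 did not pass, or 18 over the list alone (median -0.28, camera adjusted p = 1.43e-07 and 0.247). Among them was Msmo1 (-0.75 ± 0.06). By edgeR 6876 of 20998 tested genes were called, 3390 higher and 3486 lower.

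Striatal projection neuron markers were higher in 175QK772T than in 175Q as a list in the 10-week striatum, and Adora2a passed by itself. Of 16 striatal projection neuron markers, 1 rose and 15 did not pass, or 14 over the list alone (median 0.34, camera adjusted p = 4.45e-11 and 0.272). These included Adora2a (0.53 ± 0.09). Against 175Q, 126 genes were called, 117 higher and 9 lower in 175QK772T, and 124 were called the opposite way in 175Q against WT. Relative to 175Q, Gpx6 (2.08 ± 0.39), Mas1 (1.4 ± 0.23) and Robo3 (1.22 ± 0.20) were highest and Thbs1 (-0.68 ± 0.14), Dpyd (-0.55 ± 0.11) and Gprasp2 (-0.44 ± 0.07) were lowest (edgeR adjusted p at most 0.045). Against WT, edgeR called 3994 genes in 175QK772T, 1829 higher and 2165 lower, of which 3643 were called the same way in 175Q. Against WT, expression rose most in Wt1 (7.02 ± 0.36), Pou4f1 (3.65 ± 0.28) and Dsp (3.41 ± 0.36) and fell most in Gpx6 (-3.78 ± 0.30), Abhd11os (-3.64 ± 0.25) and Sec14l3 (-3.25 ± 0.29) (edgeR adjusted p at most 3.57e-05). The signature score was 1.38 ± 0.0405 in 175Q and 0.963 ± 0.0783 in 175QK772T, 69.7% of the 175Q mean. The count against 175Q changed to 34, 49 and 271 without 175QK772T replicates 1, 2 and 4 and 17, 23 and 25 without 175Q replicates 1, 2 and 3. With 1 library left out, edgeR no longer called Gpx6 (any but 175QK772T replicates 3 and 4), Mas1 (175Q replicates 1, 2 and 3), Robo3 (175QK772T replicate 1 and 175Q replicates 1 and 2), Thbs1 (any 1 of the 8), Dpyd (any but 175QK772T replicate 3) and Gprasp2 (any but 175QK772T replicates 3 and 4 and 175Q replicate 4) (adjusted p up to 0.151).

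In the striatum at 26 weeks, all 16 measured markers of striatal projection neurons fell in 175Q mice, and homeobox genes rose from 0 counts. Barx1 (at least 377-fold), Hoxb9 (at least 149-fold), Lbx1 (at least 117-fold), Hoxb8 (at least 108-fold) and Hoxc4 (at least 87.2-fold) rose from 0 counts in the WT libraries, with a floor of 3 counts over the group. AC128672.1 had 474 counts over the 4 WT libraries against 2 in the other group, a ratio of 245 with a 95% exact binomial interval of 67.6 to 2030. The largest falls were in Gpx6 (-8.19 ± 0.35), Fgf3, a fibroblast growth factor (-6.78 ± 0.66), Ptpn7 (-6.71 ± 0.51) and Cd4 (-6.06 ± 0.33) (edgeR adjusted p of all named at most 5.37e-06). Among 16 striatal projection neuron markers, 16 fell, or 16 over the list alone (median -2.88, camera adjusted p = 2.33e-14 and 0.198). Among them was Rasd2 (-3.42 ± 0.15). For microglia markers, 12 of 12 fell, or 12 over the list alone (median -0.45, camera adjusted p = 3.24e-05 and 0.282). These included Fcrls (-1.20 ± 0.09). edgeR called 8931 of 19692 tested genes, 4479 higher and 4452 lower.

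In the 26-week striatum, 15 of 16 striatal projection neuron markers were higher in 175QK772T than in 175Q. Of 16 striatal projection neuron markers, 15 rose and 1 did not pass, or 16 over the list alone (median 1.14, camera adjusted p = 1.82e-14 and 0.185). Among them was Rasd2 (1.58 ± 0.14). Among 13 targets of the repressor Capicua, 12 rose and 1 did not pass, or 13 over the list alone (median 0.75, camera adjusted p = 8.83e-09 and 0.114). These included Phlda1 (0.75 ± 0.10). 175QK772T against 175Q had 2674 called genes, 1434 higher and 1240 lower, of which 2520 were called the opposite way in 175Q against WT. In that comparison Fgf3 (4.17 ± 0.71) and Cd4 (3.47 ± 0.32) were highest and Il2rb (-1.51 ± 0.20), Baiap3 (-1.43 ± 0.21) and Plin4 (-1.41 ± 0.27) were lowest (edgeR adjusted p at most 0.00539). AC128672.1 had 34 counts over the 4 175QK772T libraries against 2 in the other group, a ratio of 17.2 with a 95% exact binomial interval of 4.4 to 148. 175QK772T had 4600 called genes against WT, 2150 higher and 2450 lower, and 4253 of these were called the same way in 175Q. Relative to WT, expression fell most in Gpx6 (-7.97 ± 0.35), Abhd11os (-4.82 ± 0.26) and Sec14l3 (-4.27 ± 0.23) (edgeR adjusted p at most 4.81e-07). Barx1 (at least 287-fold), Hoxc4 (at least 195-fold) and Hoxd8 (at least 90.7-fold) rose from 0 counts in the WT libraries, with a floor of 3 counts over the group. Signature scores were 2.53 ± 0.06 in 175Q and 1.69 ± 0.0268 in 175QK772T, 66.9% of the 175Q mean. The count against 175Q changed to 1626 and 1572 without 175QK772T replicates 2 and 3 and 1544 without 175Q replicate 2. Fgf3 gave 6.55 without 175Q replicate 4.

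**Figure D2:**
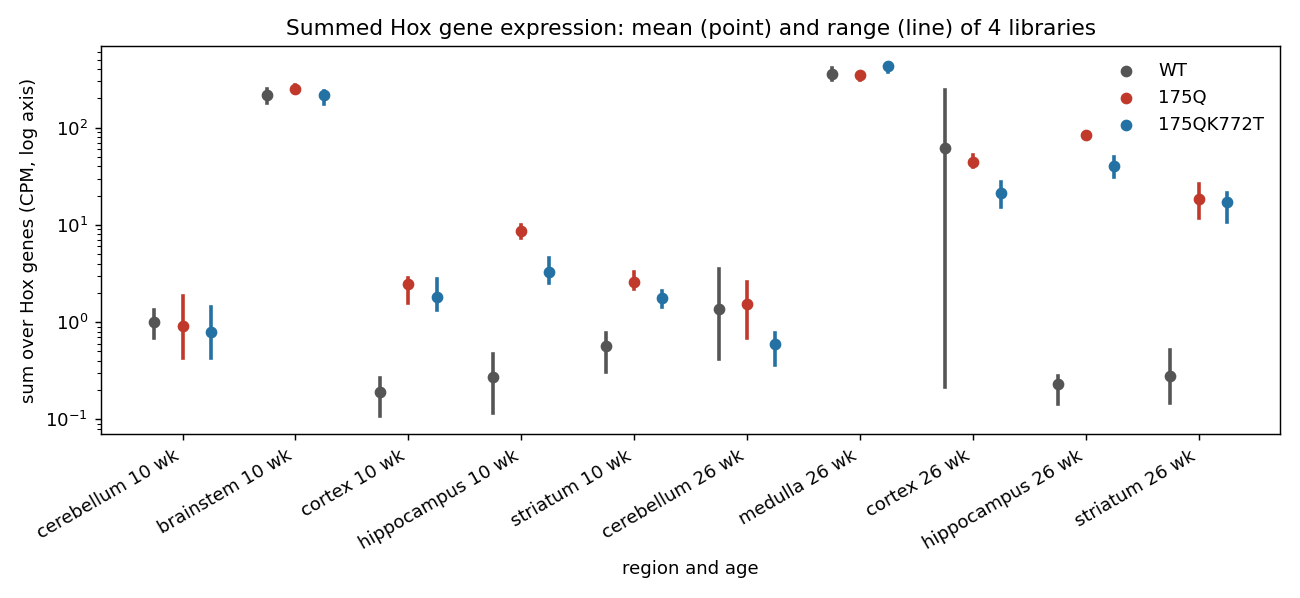
Summed expression of Hox genes (vertical axis, CPM, log axis) in each region and age (horizontal axis), as the mean (point) and range (line) of the 4 libraries of each genotype. In the hippocampus at 26 weeks the sum was 0.232 ± 0.0608 CPM in WT, 85 ± 2.04 in 175Q and 40.5 ± 7.94 in 175QK772T, and the upper end of the WT line in the 26-week cortex is WT replicate 1 at 247 CPM.

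Over the 10 sets, gene lists fixed beforehand were mostly lower in 175Q than in WT by camera. After each list stand the number of sets where it passed and, for these, the members called lower over all genes and over the list alone. They were astrocyte markers in 10 (2 to 12 of 12, 6 to 12 alone), glutamatergic synapse genes in 9 (2 to 14 of 15, 3 to 14 alone), genes of Purkinje cell calcium and mGluR1 signalling in 9 (6 to 14 of 17 to 18, 7 to 16 alone), neuronal ion channels in 9 (1 to 11 of 14, 4 to 11 alone), cholesterol synthesis genes in 8 (4 to 19 of 23, 8 to 19 alone), striatal projection neuron markers in 8 (0 to 16 of 15 to 16, 3 to 16 alone), myelin and oligodendrocyte genes in 8 (2 to 14 of 18, 1 to 18 alone) and oligodendrocyte precursor markers in 8 (2 to 8 of 10, 3 to 9 alone). Next came genes of disease-associated microglia in 7 (1 to 6 of 13 to 14, 1 to 7 alone), blood cell genes in 7 (0 to 5 of 5, 4 to 5 alone), targets of the repressor Capicua in 6 (5 to 12 of 13, 7 to 12 alone), GABAergic neuron genes in 6 (3 to 11 of 12, 4 to 11 alone), endothelial and pericyte markers in 5 (3 to 12 of 12, 4 to 12 alone), microglia markers in 5 (4 to 12 of 12, 4 to 12 alone), cortical layer markers in 5 (4 to 7 of 10, 5 to 8 alone) and Purkinje cell markers in 4 (5 to 14 of 13 to 14, 5 to 14 alone). The others were ependymal cell markers in 4 (1 to 7 of 7, 3 to 7 alone), immediate early genes in 4 (3 to 7 of 11 to 12, 3 to 9 alone), dentate gyrus and CA field markers in 3 (5 to 11 of 11, 7 to 11 alone), monoaminergic neuron genes in 2 (4 to 7 of 10, 4 to 9 alone), cholinergic and motor neuron markers in 2 (1 to 3 of 6 to 9, 3 to 4 alone), thalamic markers in 2 (2 to 3 of 7 to 8, 3 alone), choroid plexus markers in 2 (0 of 12, 0 alone), granule cell markers in 1 (7 of 12, 9 alone), reactive astrocyte genes in 1 (5 of 12, 7 alone) and glycinergic neuron genes in 1 (1 of 6, 2 alone). Higher by camera were choroid plexus markers in 2 (1 of 12, 0 to 1 alone), targets of the repressor Capicua in 1 (3 of 13, 6 alone) and immediate early genes in 1 (3 of 12, 3 alone). These 136 lower and 4 higher results had camera adjusted p of at most 0.0447, and with an estimated correlation 15 of them passed and the others gave adjusted p of up to 0.623. Ataxin-1 partner genes, heat shock chaperones and neurogenesis genes passed in no set, with unadjusted camera p under 0.05 in 3. Lists of Purkinje, striatal or cortical layer cells also passed outside their region, where they do not mark these. Against 175Q, 175QK772T had 118 lists higher and 5 lower over the 10 sets by camera, and against WT it had 91 lower and 12 higher (camera adjusted p at most 0.0497). With an estimated correlation 8 and 8 of these passed, and the adjusted p of the others was up to 0.731.

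**Figure D3:**
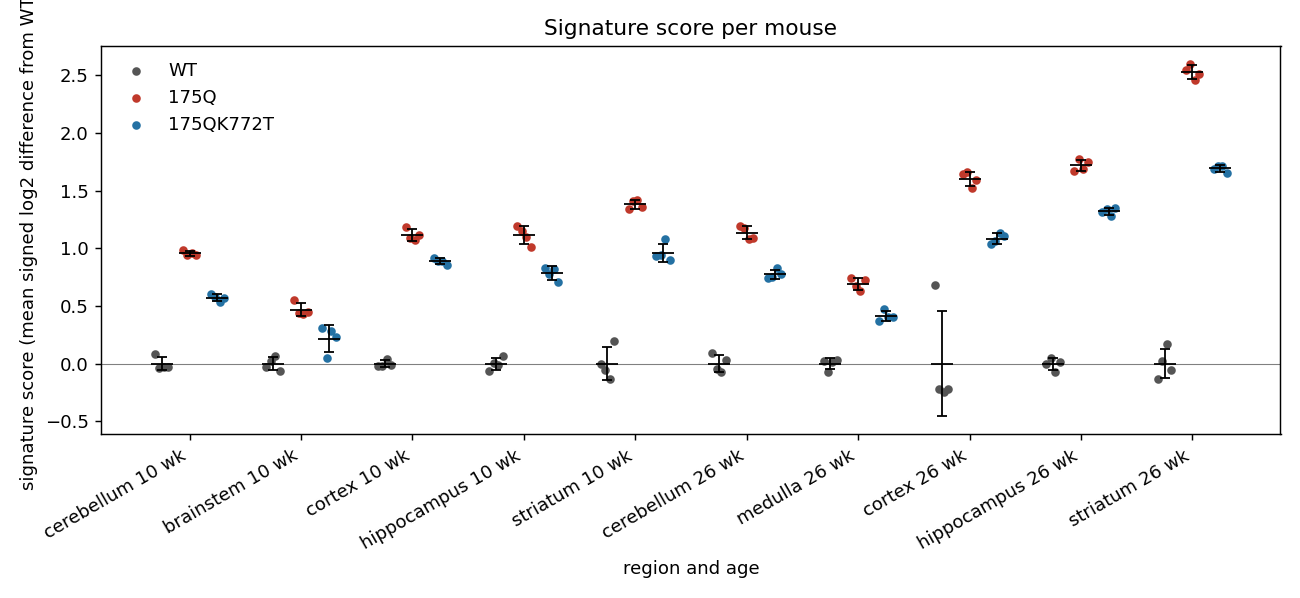
Signature score of each mouse (vertical axis, mean signed log2 difference from the WT mean over 100 genes, points) by region and age (horizontal axis), with the mean and SD of the 4 mice of each genotype. In each of the 10 sets the 4 175QK772T mice sat below the 4 175Q mice.

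The signature score sums up in each mouse the 100 genes most changed in 175Q at the other age (brainstem and medulla served for each other), signed by their direction there. 175Q differed from WT by 0.468 to 2.53, and 175QK772T differed from 175Q by -0.227 to -0.837, log2 units. In all 10 sets the 175QK772T and 175Q mice did not overlap (two-sided exact permutation p = 0.0286, adjusted p = 0.0296 over 30 tests), and this p is the smallest that 4 against 4 mice can give. The 5 regions of an age came from the same mice and are not independent.

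Some genes moved the same way in most regions of 175Q mice. At 10 weeks 200 genes were called higher and 407 lower in at least 4 of 5 regions, with 19 and 55 in all 5, and at 26 weeks 727 and 819 in at least 4, with 33 and 90 in 5. By mean rank at 10 weeks the first were Sema7a (-1.36 to -0.36), Plk5 (-3.03 to -0.56), Hrh3 (-2.15 to -0.67), Polr2a (0.37 to 0.77), Kcnh3 (-2.50 to -0.79), Zmynd8 (-0.71 to -0.15), Neto2 (-1.5 to -0.30), Gprasp2 (0.18 to 1.18), Gprasp1 (0.17 to 0.75) and Usp11 (0.19 to 0.72), as the range of log2 fold changes over 5 regions. Polr2a encodes the largest subunit of RNA polymerase II, Hrh3 a histamine receptor and Neto2 a kainate receptor partner. At 26 weeks they were Polr2a (0.60 to 1.38), Htr1b (-3.51 to -0.87), Gsg1l (-3.62 to -0.55), Usp11 (0.39 to 1.01), Fads1 (-0.83 to -0.48), Asl (0.46 to 1.62), Tyro3 (-1.55 to -0.31), Camkk2 (-1.85 to -0.30), Plk5 (-2.34 to -0.94) and Cirbp (0.67 to 0.99). Htr1b encodes a serotonin receptor, Fads1 a fatty acid desaturase, Asl argininosuccinate lyase and Cirbp a cold-inducible RNA-binding protein. edgeR called Tyro3 in 4 regions and the other 19 in 5.

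Whether the 175Q effect differed between ages was tested by an edgeR interaction term, in which age, sequencing batch and the line, which the 26-week descriptions name otherwise, cannot be told apart. In the cerebellum 4 of 20530 genes were called, and of 4 measured at both ages 4 had the same direction with the larger change at 26 weeks and 0 had opposite signs. This count was 0 without WT 10 weeks replicate 2, 2 without 175Q 10 weeks replicate 3, 2 and 0 without WT 26 weeks replicates 2 and 3 and 234 without 175Q 26 weeks replicate 4. These genes, outside the rule for names and chosen after their values were seen, were Slc7a3 (-1.25 ± 0.17), Hrk (1.38 ± 0.17), Kctd12 (-0.64 ± 0.09) and Gm12198 (-1.39 ± 0.17). In the cortex 145 of 21188 genes were called, and of 145 measured at both ages 102 had the same direction with the larger change at 26 weeks and 40 had opposite signs. This count was 1838 without WT 26 weeks replicate 1 and 31 to 94 without any 1 of the other 15 libraries. In the hippocampus 1578 of 21240 genes were called, and of 1566 measured at both ages 1153 had the same direction with the larger change at 26 weeks and 398 had opposite signs. This count was 1014 without WT 10 weeks replicate 3. In the striatum 1872 of 21214 genes were called, and of 1849 measured at both ages 1513 had the same direction with the larger change at 26 weeks and 320 had opposite signs. This count was 1240 without 175Q 10 weeks replicate 1. Called at both ages with the same sign were 393, 4302, 3189 and 5265 genes in these regions in turn, and with opposite signs 0, 26, 22 and 37.

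Over the 10 sets, 80.8 to 100% of the genes called in 175QK772T against WT were called in the same direction in 175Q, and 72.4 to 100% of those called in 175QK772T against 175Q had been called the opposite way in 175Q against WT. These comparisons share libraries. In 5 simulations per set with no changed gene a mean of at most 0.4 called genes were shared, which gives no value to set these shares against. The covariance of log2 fold changes was 0.053 to 0.433 (simulated 0.0229 to 0.0448) for the same direction and 0.0565 to 0.252 (0.0226 to 0.0458), with the sign turned, for the opposite. With the shared group split so that no library served in both, the 2 assignments gave 2565 and 3095 against 4253 genes of the same direction in the 26-week striatum. Genes of opposite direction were 1168 and 611 against 2520 there, 124 and 11 against 657 in the 26-week cortex, 4 and 12 against 206 in the 10-week cortex and 7 and 5 against 124 in the 10-week striatum.

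Genes near Atxn1 were compared with the rest, since variants linked to a knock-in can change its neighbours. Within 10 Mb, 54.9% of 164 tested genes were called for 175Q against WT in the striatum at 26 weeks and 45.3% elsewhere (odds ratio 1.47, 95% interval 1.07 to 2.03, Fisher's exact test p = 0.0146, adjusted p = 0.115). Over the 30 comparisons the adjusted p of Fisher's exact test was 0.115 to 1, with an unadjusted p under 0.05 in 9.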

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

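The tests of the doubted cortex library, of Hox genes and of single genes near Atxn1 were chosen after the results were seen, and the other splits of the samples and the test of the Atxn1 neighbourhood beforehand. In 120 tests over 4 measures of the 30 groups of 4 libraries, 10 had a library far from the other 3, where chance gives about 1 in 20 or 6. The share of counts from mitochondrial genes in the 26-week cerebellum was 4.89% in WT replicate 1 (others 3.9 to 4.03%), 11.5% in 175QK772T replicate 2 (3.91 to 5.01%) and 13.5% in 175Q replicate 4 (3.89 to 4.04%), and in the 26-week hippocampus 4.98% in WT replicate 2 (5.56 to 5.67%). In the same 2 mutant cerebellum libraries Atxn1 was at 43 CPM (175QK772T replicate 2, others 59.9 to 62.9) and 49.1 CPM (175Q replicate 4, others 60.4 to 62.4). The signature score stood apart in WT replicate 1 of the 10-week cerebellum (0.0879, others -0.0334 to -0.0261), 175Q replicate 1 of the 10-week brainstem (0.55, others 0.434 to 0.45), WT replicate 3 of the 10-week cortex (0.0432, others -0.0179 to -0.00766) and WT replicate 1 of the 26-week cortex (0.686, others -0.248 to -0.218).

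WT replicate 1 of the 26-week cortex, labelled female, held Y-linked Ddx3y at 70.2 CPM, against 0 in the other female libraries there. A whole library of another region or mouse is argued against by Xist at 290 CPM, 17.4% of the female cortex mean. Male libraries there had at most 0.27 CPM. RNA of a male medulla library mixed into it is a candidate. A fit to region profiles gave the medulla 74.9%, against at most 0.695% in the other 3 WT cortex libraries. It also gave 13.5 to 16.3% in 175Q cortex and 14 to 33.5% in 175Q hippocampus, so the fit alone does not show mixing. Abundant transcripts moved alike, with Mbp at 7070 CPM (2560 ± 231 in the other 3), Ttr at 2570 and Slc17a7 at 268 (1030 ± 12.7). The step of mixing stays open, and no biological explanation was tested.

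Hox genes, which pattern the hindbrain and spinal cord, were called higher in 175Q than in WT by edgeR for 7 of 23 tested in the 26-week cortex (24 of 24 without WT replicate 1), 28 of 28 in the hippocampus and 13 of 13 in the striatum. Hindbrain tissue in the 175Q dissections is argued against because 4, 13 and 4 Hox genes in these regions in turn were above every WT and 175Q medulla library, and greater depth because the mean total of 175Q was at most 0.929 times that of WT. Spinal cord was not sampled, so tissue from it stays open, with other medulla markers (Slc6a5 and Glra1 in each region) rising by a median of 0.514, 0.394 and 0.286% of the medulla level (up to 9.12, 5.4 and 115%) and Hox markers by 2.83, 9.51 and 1.13% (up to 15.7, 26.2 and 7.05%). Dependence on nuclear entry of expanded ataxin-1 stays open. Of the called Hox genes, 28.6% were lower in 175QK772T than 175Q and 0 higher (median -1.33) in the cortex. It was 50% and 0 (-0.94) in the hippocampus and 0% and 2 (-0.23) in the striatum. Being chosen as high in the same 175Q libraries lowers these medians. Sums of Hox genes in 175Q and 175QK772T were 44.6 ± 5.6 and 21.5 ± 5.47 CPM in the cortex. In the hippocampus they were 85 ± 2.04 and 40.5 ± 7.94, in the medulla 347 ± 23.7 and 428 ± 36.3. In the striatum they were 18.3 ± 7.65 and 17.1 ± 4.61. Outside the striatum these did not overlap (two-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0572), so not passing decides little.

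Whether variants linked to the knock-in change genes near Atxn1 stays open. Of 20 contrasts of a mutant with WT, 0 had calls enriched within 10 Mb (Fisher's exact test, adjusted p below 0.05, set beforehand). A missed threshold excludes nothing, and the unadjusted p was under 0.05 in 9. At single genes, 4 of 204 within 10 Mb and 343 of 23254 elsewhere were called the same way in both mutants in at least 6 of 10 sets (odds ratio 1.34, Fisher's exact test p = 0.55). Those near, named after seeing values, were A330076C08Rik, Cplx2, Diras2 and Fbxw17. Barx1, 3.11 Mb away, rose in 5 sets in each mutant (median 9.52 and 7.71).

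All 35 splits of the 8 libraries of each contrast were tried. Taken 1 by 1, uncorrected, chance was excluded in 28 of 30 contrasts, where only 1 split, the real one, called as many genes. The real count and the highest other were, for 175Q against WT, at 10 weeks 2330 and 1 in the cerebellum, 619 and 0 in the brainstem, 7936 and 3 in the cortex, 4132 and 1 in the hippocampus and 6876 and 0 in the striatum, and at 26 weeks 576 and 55 in the cerebellum, 3663 and 0 in the medulla, 6275 and 701 in the cortex, 8073 and 2 in the hippocampus and 8931 and 0 in the striatum. For 175QK772T against WT they were at 10 weeks 826 and 0 in the cerebellum, 5364 and 0 in the cortex, 2273 and 0 in the hippocampus and 3994 and 0 in the striatum, and at 26 weeks 57 and 0 in the cerebellum, 412 and 171 in the medulla, 1756 and 0 in the cortex, 3765 and 0 in the hippocampus and 4600 and 1098 in the striatum. For 175QK772T against 175Q they were at 10 weeks 244 and 1 in the cerebellum, 12 and 0 in the brainstem, 217 and 2 in the cortex and 126 and 0 in the striatum, and at 26 weeks 19 and 0 in the cerebellum, 1872 and 22 in the medulla, 688 and 0 in the cortex, 3107 and 13 in the hippocampus and 2674 and 15 in the striatum. Chance was not excluded for 175QK772T against WT in the 10-week brainstem (real 7, highest other 333, 2 of 35 splits with as many) and for 175QK772T against 175Q in the 10-week hippocampus (real 7, highest other 195, 4 of 35). The split with 333 set WT replicates 1 and 2 with 175QK772T replicates 2 and 3 against the rest, and that with 195 set 175QK772T replicate 1 with 175Q replicates 1, 2 and 3, which points to a structure of these samples other than genotype. In the brainstem it followed the choroid plexus transcript Ttr, at 8.33 to 100 CPM in the first 4 libraries and 1780 to 4810 in the rest.

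The 175Q effect differed between ages by the interaction test in 4 genes in cerebellum, 145 in cortex, 1578 in hippocampus and 1872 in striatum. Whether chance gives as many stays open. Of 100 drawn splits 3 called as many in each, the real one included, with highest other counts of 10, 504, 3971 and 5151, but splits that mix genotypes carry the genotype effect as spread and called a median of 0 genes. Those with the highest counts kept the genotypes apart at 1 age and mixed them at the other: a structure of the samples. In the cerebellum the count was 0 with the replicate block and without WT replicate 2 of 10 weeks or 3 of 26 weeks. Age, sequencing batch and line cannot be told apart, and the difference was not weighed further.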

How the results depend on the processing

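Most alternatives were chosen beforehand, and those without the 2 libraries of high mitochondrial share or the doubted WT library of the 26-week cortex after seeing the data. Of 34 counts of called genes, 34 stayed within 1.5 times under RLE normalization, and the shift of the median gene between scalings was at most 0.015 (log2). DESeq2 moved 17 counts. With DESeq2, 175Q against WT had 1348 in the 10-week brainstem and 1241 in the 26-week cerebellum; 175QK772T against WT had 1336 in the 10-week cerebellum, 147 in the 10-week brainstem, 330 in the 26-week cerebellum, 933 in the 26-week medulla and 2707 in the 26-week cortex; 175QK772T against 175Q had 560 in the 10-week cerebellum, 184 in the 10-week brainstem, 785 in the 10-week cortex, 189 in the 10-week hippocampus, 628 in the 10-week striatum, 352 in the 26-week cerebellum and 1746 in the 26-week cortex; the difference between ages had 89 in the cerebellum, 577 in the cortex and 2378 in the hippocampus. It moved the share of calls that were higher by over 10 percentage points: for 175QK772T against 175Q, 83.2 from 93.4% in the 10-week cerebellum, 59.6 from 72.4% in the 10-week cortex, 71.4 from 28.6% in the 10-week hippocampus and 61.6 from 89.5% in the 26-week cerebellum; for 175QK772T against WT, 52.4 from 14.3% in the 10-week brainstem and 33.9 from 22.8% in the 26-week cerebellum; for the difference between ages, 39.3 from 25% in the cerebellum. RLE did so to 16.7 from 28.6% for 175QK772T against 175Q in the 10-week hippocampus and 35.2 from 45.4% for the difference between ages in the striatum. This share moved so in 11 counts with no low-count filter (furthest to 74.7 from 28.6% for 175QK772T against 175Q in the 10-week hippocampus), 2 with the block, 1 with no sex term, 3 without the 2 mitochondrial libraries, 1 without the 175Q one and 1 without the doubted library. Leaving out 1 library moved it so, at its furthest to these values: for 175Q against WT, 22.2 from 36% in the 10-week brainstem; for 175QK772T against WT, 40 from 14.3% in the 10-week brainstem and 10.5 from 22.8% in the 26-week cerebellum; for 175QK772T against 175Q, 83.7 from 72.4% in the 10-week cortex, 100 from 28.6% in the 10-week hippocampus, 0 from 89.5% in the 26-week cerebellum, 68.7 from 55.4% in the 26-week cortex and 71.1 from 53.6% in the 26-week striatum; for the difference between ages, 55.6 from 25% in the cerebellum, 32.7 from 56.6% in the cortex, 55.2 from 34.7% in the hippocampus and 27.3 from 45.4% in the striatum. No low-count filter, which tests more genes, moved 16. Without the filter, 175Q against WT had 1744 in the 10-week brainstem and 1042 in the 26-week cerebellum; 175QK772T against WT had 1418 in the 10-week cerebellum, 372 in the 10-week brainstem, 447 in the 26-week cerebellum, 1351 in the 26-week medulla and 3105 in the 26-week cortex; 175QK772T against 175Q had 942 in the 10-week cerebellum, 439 in the 10-week brainstem, 938 in the 10-week cortex, 368 in the 10-week hippocampus, 1285 in the 10-week striatum, 252 in the 26-week cerebellum and 1660 in the 26-week cortex; the difference between ages had 9 in the cerebellum and 1445 in the cortex. No sex term moved 3. Without this term, 175QK772T against WT had 11 in the 10-week brainstem; 175QK772T against 175Q had 207 in the 10-week striatum and 12 in the 26-week cerebellum. The labels do not pair mice across genotypes. In 0 of 30 contrasts did all 4 same-numbered pairs deviate together with a correlation over 0.1. Of all, 25 of 120 libraries correlated best with their own number. A replicate block leaves fewer residual degrees of freedom and moved 14. With the block, 175Q against WT had 314 in the 10-week brainstem; 175QK772T against WT had 0 in the 10-week brainstem and 1307 in the 10-week hippocampus; 175QK772T against 175Q had 143 in the 10-week cerebellum, 2 in the 10-week brainstem, 50 in the 10-week cortex, 2 in the 10-week hippocampus, 56 in the 10-week striatum, 6 in the 26-week cerebellum, 253 in the 26-week cortex and 1719 in the 26-week striatum; the difference between ages had 0 in the cerebellum, 6 in the cortex and 1205 in the striatum. Without the 2 libraries of high mitochondrial share the counts in the 26-week cerebellum were 2608 for 175Q against WT, 702 for 175QK772T against WT and 1682 for 175QK772T against 175Q, and the difference between ages in the cerebellum counted 234 without the 175Q one. With the doubted WT library left out they were 4738 for 175QK772T against 175Q in the 26-week cortex and 1838 for the difference between ages in the cortex. Except where fewer residual degrees of freedom or a wider set of tested genes is named, the cause was not tested.

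Leaving out 1 library at a time gave 304 counts, of which 191 were within 1.5 times of the full count. Over these fits, 175Q against WT had 203 to 587 in the 10-week brainstem, 202 to 669 in the 26-week cerebellum and 2323 to 3089 in the 26-week medulla. 175QK772T against WT had 514 to 951 in the 10-week cerebellum, 3 to 11 in the 10-week brainstem, 1271 to 1961 in the 10-week hippocampus, 16 to 35 in the 26-week cerebellum, 210 to 926 in the 26-week medulla and 930 to 4641 in the 26-week cortex. 175QK772T against 175Q had 148 to 205 in the 10-week cerebellum, 1 to 4 in the 10-week brainstem, 34 to 255 in the 10-week cortex, 1 to 9 in the 10-week hippocampus, 17 to 271 in the 10-week striatum, 1 to 44 in the 26-week cerebellum, 730 to 1838 in the 26-week medulla, 119 to 325 in the 26-week cortex, 1982 to 3055 in the 26-week hippocampus and 1544 to 2893 in the 26-week striatum. The difference between ages had 0 to 234 in the cerebellum, 31 to 1838 in the cortex, 1014 to 1713 in the hippocampus and 1240 to 2416 in the striatum. These fits compare 3 with 4 mice, and the cause was not tested beyond that.

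When the shared group was split so that no library served in both comparisons, which leaves 2 mice on each side of it, genes shared by 175Q against WT and 175QK772T against WT numbered, for the 2 assignments, 412 and 333 in the 10-week cerebellum, 1 and 3 in the 10-week brainstem, 3441 and 3165 in the 10-week cortex, 886 and 978 in the 10-week hippocampus, 1904 and 2165 in the 10-week striatum, 14 and 13 in the 26-week cerebellum, 112 and 119 in the 26-week medulla, 894 and 1325 in the 26-week cortex, 2220 and 1909 in the 26-week hippocampus and 2565 and 3095 in the 26-week striatum. Those called the opposite way in 175QK772T against 175Q numbered 89 and 133 in the 10-week cerebellum, 1 and 0 in the 10-week brainstem, 4 and 12 in the 10-week cortex, 4 and 0 in the 10-week hippocampus, 7 and 5 in the 10-week striatum, 3 and 0 in the 26-week cerebellum, 309 and 342 in the 26-week medulla, 124 and 11 in the 26-week cortex, 1918 and 1146 in the 26-week hippocampus and 1168 and 611 in the 26-week striatum. Of 366 gene list results that passed by camera, 31 passed with an estimated correlation.

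Of 1263 log2 fold changes of named genes with a DESeq2 value, 2 lost their call with it. Of 1265, 5 lost theirs with RLE normalization, 10 with no low-count filter, 40 with no sex term and 132 with the replicate block, and 1101 of 10120 values with 1 library left out lost theirs. Signs turned in 13 values, all of Atxn1 where it was not called. With 1 library left out its value ranged from -0.10 to 0.00116 for 175Q against WT in the 10-week striatum, -0.0135 to 0.18 for 175Q against WT in the 26-week cerebellum, -0.0582 to 0.18 for 175QK772T against WT in the 26-week cerebellum, -0.0969 to 0.0686 for 175QK772T against 175Q in the 26-week cerebellum (0.00873 without the 2 libraries of high mitochondrial share), -0.0762 to 0.0174 for 175QK772T against 175Q in the 26-week medulla and -0.0932 to 0.0447 for 175QK772T against WT in the 26-week striatum. The cause was not tested. Of the 30 score differences, all kept their direction under every alternative run; with 300 genes the 10-week brainstem difference for 175QK772T against WT (0.158) passed, and with genes chosen without the doubted WT library the 10-week cortex differences from WT were 1.37 in 175Q and 1.13 in 175QK772T. Genes within 5 or 20 Mb of Atxn1 gave 0 comparisons passing by Fisher's exact test, like 10 Mb. Depth and spread limit small changes, as in the simulations above.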

Other observations

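Genes at least 2-fold higher in 1 forebrain region than in any other region of WT at 10 weeks, with at least 5 CPM, were followed at 26 weeks as that region's own, a measure chosen after the results were seen. In the cortex the doubted WT library was left out of the medians. At 26 weeks edgeR called 70 of 116 such genes lower in the 175Q cortex, 102 of 122 in the hippocampus and 187 of 209 in the striatum, against 3231 of 19888, 4043 of 19809 and 4452 of 19692 of all tested. Of genes at least 2-fold lower there than in every other region, 4 of 25, 5 of 21 and 3 of 57 were called lower. The median log2 change per mouse of the first, in 175Q and 175QK772T in turn, was -0.899 ± 0.0567 and -0.454 ± 0.0463 in the cortex, -0.698 ± 0.0701 and -0.464 ± 0.0604 in the hippocampus and -1.42 ± 0.134 and -0.975 ± 0.25 in the striatum.

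Summed Hox expression was also higher at 10 weeks, at 8.68 ± 1.21 CPM in the 175Q hippocampus against 0.27 ± 0.148 in WT. The two-sided exact permutation p = 0.0286 is the smallest possible, and adjusted p = 0.0572 over 30 tests did not pass. In the cerebellum at 10 weeks it was 0.913 ± 0.645 CPM in 175Q and 0.997 ± 0.295 in WT.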
